A study of Mus musculus with 10 samples.

How the data were processed

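Expression was measured on 1-colour Affymetrix arrays in the aorta of male C57BL/6 mice, wild type or lacking Ptgds. The series lists 10 samples, called biological replicates in the labels: 5 wild type and 5 knockout. The column of wild type replicate 2 holds 0 values, and per the labels that sample was excluded, so 9 arrays entered every comparison (wild type replicates 1, 3, 4 and 5, and knockout replicates 1 to 5). The labels name no substrain, no litter, no scan batch and no hour of dissection.

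The deposited values were made by the authors with GCRMA, per the submitters' processing notes, which corrects background, normalizes across arrays and gives 1 value per probe set; its version and scale are not stated. The deposited values were read as log2, since every array runs from about 2 to 15 with like quartiles. That scale is an inference from the values and not a statement of the labels. No values were scaled or centred again, and no replicates were pooled. The number of arrays limits the precision of every value.

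Of the 45101 probe sets, 34945 carry 1 gene symbol in the platform annotation, 932 carry several, 9211 carry none or are not listed there, and 64 are controls, some of which are also among those without a symbol; 0 symbols needed an update through the gene identifier. Controls and probe sets with several symbols or none were left out. A probe set was tested if its log2 value was over 4 on at least 4 arrays, the size of the smaller group, which left 26504 probe sets with 1 gene. A gene was represented by its probe set with the highest mean over all arrays, and 14321 genes were tested.

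Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2 groups, no covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Changes are knockout minus wild type on the log2 scale, with the standard error (SE) of the moderated fit; levels are means with the standard deviation (SD). Values of 1 measure per array were compared by exact two-sided permutation over all 126 splits of 4 against 5 arrays, whose smallest p is 0.0079, adjusted over 16 measures.

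33 gene lists were tested with camera (limma, preset correlation 0.01), adjusted over the lists, with an estimated correlation and with fry as alternatives. Together with the sex-linked sample check genes they hold 853 genes, of which 780 are named on the array and 719 were tested. Sample check genes entered no list test, and each list had at least 5 tested members. 4 lists follow known roles of the enzyme (prostanoid synthesis and receptors, vasoactive genes, thrombosis and fibrinolysis, contractile smooth muscle); the others are pathways and markers of cell types that an aorta preparation can hold. Members were also adjusted over each list alone.

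The targeted allele could keep neighbouring DNA of another strain, so called genes were counted among the 100 tested genes on each side of Ptgds and compared with all others by Fisher's exact test, two-sided. The deposited values name no genome build, so gene order was taken from the assembly GRCm38.p6 for 14287 tested genes and no coordinates are given; the 34 tested genes without a position were counted as lying elsewhere.

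Genes were named by this rule: Ptgds; among genes past the threshold whose groups do not overlap, the 12 with the largest rise and the 12 with the largest fall, filled to 8 in a direction with the smallest p-values where fewer passed, these being given as values; the 3 members with the smallest p of each list on the enzyme's roles and of each other list past the camera threshold; and sample check genes. The design, the lists, this rule and the alternatives not called later additions were fixed before the data were examined.

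The procedure was tested on simulated data made from these arrays: 14321 genes, 4 against 5 arrays, 200 genes changed in each of 10 runs. It called 62.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 95.8% of those changed 4-fold, with a mean of 10 false calls per run. A shifted list was found in 10 of the 10 runs and an unshifted list in 0. The simulated noise was independent between genes, and all members of a shifted list moved by the same amount. In the real arrays list members move together, with an estimated correlation of up to 0.95 (neuron markers). The simulated rates therefore do not hold for the real lists. The gene rates hold only for 200 changed genes beside a shifted list, with independent noise. How small a p must be to pass the adjustment depends on how many genes change. These rates are therefore not the power of the real comparison.

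Alternatives were quantile normalization again, array medians set to 0, no filter or a floor of 6, other rules for a gene's probe sets, limma with trend and robust options, array weights, a looser threshold, a fold of at least 1.5 as a further condition, the mean of the adipocyte markers as a covariate, the replicate number as a block, leaving out each array in turn, other windows around Ptgds, and the median of the members in place of the mean for the array measures. Leaving out the 2 arrays with most neuronal transcripts, and covariates for neuron markers and for the 3' to 5' ratio of the Gapdh controls, were added after seeing the data.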

Results

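Total RNA from the aorta of male C57BL/6 mice was profiled on Affymetrix arrays of 45101 probe sets. The arrays with values held 4 wild type and 5 knockout biological replicates. Knockout mice lacked Ptgds, the gene of lipocalin-type prostaglandin D synthase (L-PGDS), which makes prostaglandin D2. Median log2 values were 5.97, 5.96, 5.91 and 5.92 on wild type replicates 1, 3, 4 and 5, and 5.95, 5.94, 5.95, 5.95 and 5.88 on knockout replicates 1 to 5. Between 70.1% and 71.4% of the probe sets lay over a log2 value of 4 on each array. Eif2s3y, a Y-linked gene, lay between 11.63 and 11.89 on all 9 arrays, and 3 probe sets of Xist lay between 2.61 and 3.96; all arrays are labelled male. The arrays correlated with the others at a mean of 0.984 to 0.987, except wild type replicate 3 at 0.969.

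The comparison asks how the transcripts of the aorta differ between mice with and without L-PGDS. Ptgds itself stood at 9.22 ± 0.75 (SD, n = 4) in wild type and at 3.92 ± 0.29 (SD, n = 5) in knockout aortas on probe set 1423859_a_at. That is a change of −5.30 (log2, SE 0.32), or 39.4-fold lower, with an adjusted p of 0.00059 (limma). The knockout mean lies under the floor of 4, so the size of the fall depends on the background and is not exact. All 5 knockout arrays lay below all 4 wild type arrays, an exact permutation p of 0.0079, the smallest that these groups allow. On the knockout arrays this probe set ranked at the 24.9th to 33.7th percentile of all probe sets. The other probe set, 1423860_at, went from 5.93 ± 0.86 (SD, n = 4) to 4.13 ± 0.17 (SD, n = 5), a change of −1.80 (SE 0.34) with an adjusted p of 0.113 over all named probe sets (limma) and the same exact permutation p of 0.0079. The labels do not say which exons the allele lacks or where the probes lie, and a probe set outside the deleted part would check nothing. Ptgds kept its call when any 1 array was left out, with a highest adjusted p of 0.0051.

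Beside Ptgds, 7 genes differed between the genotypes, and 4 of them were higher in the knockout aortas. Prtg, which encodes the immunoglobulin superfamily protein protogenin, rose from 5.25 ± 0.16 to 6.34 ± 0.09 (SD, n = 4 and 5), 2.13-fold. Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, rose by 0.70 (SE 0.08, 1.63-fold), Atp2b4, a plasma membrane calcium pump, by 0.80 (SE 0.10, 1.74-fold), and Pisd-ps3, a pseudogene of phosphatidylserine decarboxylase, by 1.02 (SE 0.13, 2.03-fold). The transcript G530011O06Rik fell 11.1-fold (−3.48, SE 0.37), from 10.56 ± 0.44 to 7.08 ± 0.74 (SD, n = 4 and 5). Mid1, which encodes a ubiquitin ligase bound to microtubules, fell 5.63-fold (−2.49, SE 0.30), and Gm13306 fell 3.30-fold (−1.72, SE 0.18). Mid1 and G530011O06Rik are neighbours in the gene order of GRCm38.p6. The adjusted p (limma) was 0.0028 for Prtg, 0.023 for Nnt, 0.042 for Atp2b4, 0.039 for Pisd-ps3, 0.021 for G530011O06Rik, 0.035 for Mid1 and 0.021 for Gm13306. Further probe sets of these genes had changes of the same sign: 4 of Pisd-ps3 by 1.01 to 2.29, 1 of Prtg by 0.64, and 2 of Nnt by 1.33 and, at a level near 4.22, by 0.09. Over all named probe sets their adjusted p (limma) was 0.00073 to 0.047 for Pisd-ps3, 0.103 for Prtg, and 0.0050 and 0.733 for Nnt. Atp2b4, G530011O06Rik, Mid1 and Gm13306 had no further tested probe set, so each of these changes rests on 1. The knockout mean of Mid1 was 4.55, near the floor of 4, so the size of its fall is not exact.

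**Figure D1:**
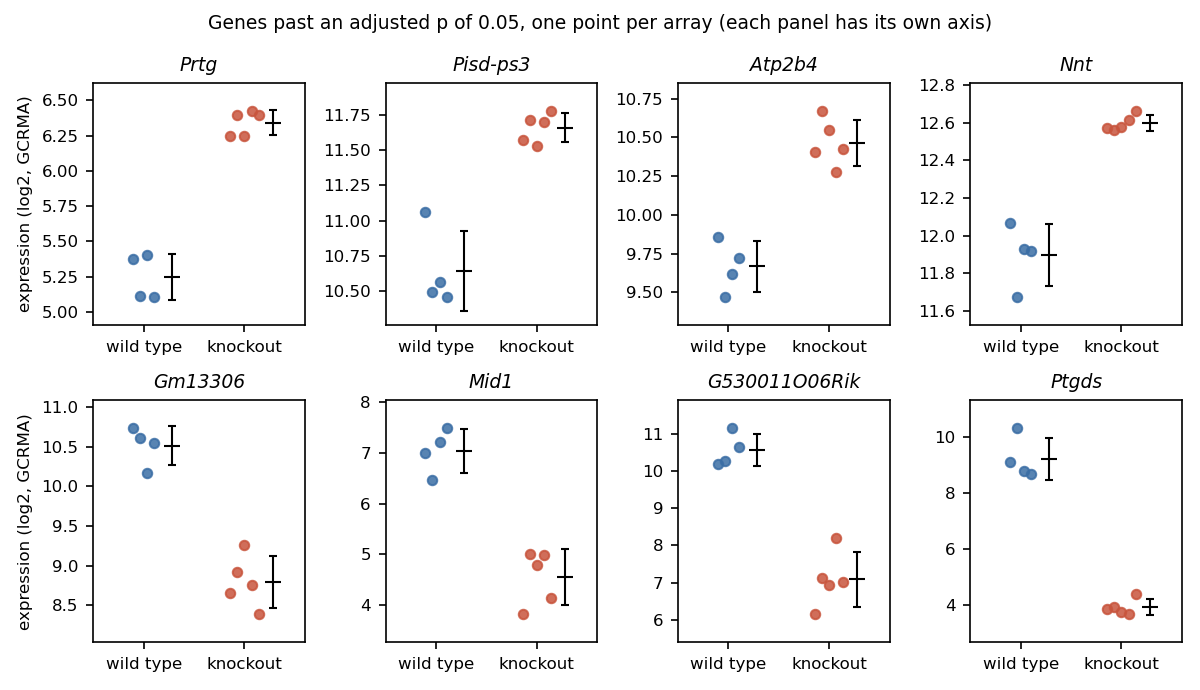
Expression (log2, GCRMA) of the 8 genes past an adjusted p of 0.05, with 1 point per array (4 wild type, blue, and 5 knockout, red) and the mean ± SD beside the points; each panel has its own axis. The groups do not overlap for any of the 8 genes, and Ptgds went from a mean of 9.22 to 3.92.

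In all, 8 of 14321 genes passed an adjusted p of 0.05, 4 higher and 4 lower in the knockout. At an unadjusted p under 0.05 there were 2847 genes, 1828 higher and 1019 lower, where chance gives about 716. The groups did not overlap for 968 genes, 6.76% of those tested, against 1.59% by chance. Genes move together on these arrays, so such counts can lie far from the chance average. Neither excess by itself measures an effect of genotype. Each limma p-value sets the group difference against the spread between these biological replicates, moderated over all genes. The count of 8 depended on single arrays: it was 1051 without wild type replicate 1, 16 without knockout replicate 4, 4 without knockout replicate 3, 3 without any 1 of wild type replicates 3 and 4 and knockout replicates 1 and 5, and 2 without wild type replicate 5 or knockout replicate 2. Ptgds and Prtg passed in all 9 of these fits, Gm13306 in 5, Nnt and G530011O06Rik in 3, Atp2b4 and Mid1 in 2, and Pisd-ps3 in 1. Each gene was represented there by its brightest probe set alone.

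Genes just short of the threshold are given as values. Among those higher in the knockout, Setd6, a lysine methyltransferase, stood at +0.46 (SE 0.06, adjusted p 0.055), Phxr4 at +0.59 (SE 0.08, adjusted p 0.063), Tcea3, a transcription elongation factor, at +0.67 (SE 0.10, adjusted p 0.063) and Akap5, a kinase anchoring protein, at +0.70 (SE 0.10, adjusted p 0.070). Among those lower, Lrmda stood at −1.51 (SE 0.20, adjusted p 0.055), the galactosyltransferase gene B4galt5 at −0.50 (SE 0.07, adjusted p 0.055), D2hgdh, which oxidises D-2-hydroxyglutarate, at −0.68 (SE 0.10, adjusted p 0.070) and the dipeptidase gene Cndp2 at −0.38 (SE 0.06, adjusted p 0.079). Other tested probe sets stood at −0.039 (SE 0.10) for B4galt5, 0.0090 and 0.33 for Akap5, 0.51 and 0.18 for Setd6, −0.75 for D2hgdh and −0.51 for Cndp2, so the fall of B4galt5 rests on 1 of its 2 probe sets and the rise of Akap5 mainly on 1 of 3.

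Genes of the prostanoid pathway did not shift past the test. Of 27 tested synthases, receptors and related enzymes, 12 were higher and 15 lower in the knockout, with a median change of −0.016. The strongest were Alox12, an arachidonate lipoxygenase, at +0.59 (SE 0.18, adjusted p 0.153), the thromboxane receptor gene Tbxa2r at +0.33 (SE 0.11, adjusted p 0.173) and the prostaglandin E2 receptor gene Ptger2 at −0.52 (SE 0.19, adjusted p 0.191). 0 members passed in limma when adjusted over the list alone or over all genes, and 3 had an unadjusted p under 0.05. The list's adjusted p was 0.159 (camera), and it passed, toward lower values, without wild type replicate 4 (median −0.11, adjusted p 0.020).

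Vasoactive genes and genes of thrombosis and fibrinolysis were likewise spread around 0. Among 46 vasoactive genes, 26 were higher and 20 lower: Gucy1a1, a subunit of the nitric oxide receptor, stood at +0.39 (SE 0.09, adjusted p 0.110), Ramp1, part of the receptor for calcitonin gene-related peptide, at +0.38 (SE 0.10, adjusted p 0.134) and haem oxygenase Hmox1 at −0.43 (SE 0.12, adjusted p 0.136). The median was 0.015 and the mean −0.020, and camera placed the list lower (adjusted p 0.699). Among 33 genes of thrombosis and fibrinolysis, 18 were higher and 15 lower. The integrin gene Itgb3 stood at +0.45 (SE 0.12, adjusted p 0.134), Anxa2, a plasminogen-binding annexin, at −0.22 (SE 0.06, adjusted p 0.147) and thrombospondin Thbs1 at −1.07 (SE 0.35, adjusted p 0.164). Their median was 0.0023 and their mean 0.022, while camera placed the list lower relative to other genes (adjusted p 0.686). Without any 1 array the median ran from −0.0040 to 0.034 for vasoactive genes and from −0.019 to 0.032 for thrombosis and fibrinolysis, so neither has a stable direction. In both lists 0 members passed in limma, adjusted over the list alone or over all genes; unadjusted p-values under 0.05 numbered 7 among vasoactive genes and 4 in thrombosis and fibrinolysis.

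Contractile smooth muscle genes lay slightly higher in the knockout, in 24 of 29 members, with a median of 0.077 against 0.027 over all tested genes. Ppp1r14a, an inhibitor of myosin phosphatase, stood at +0.33 (SE 0.06), the myosin light chain gene Myl9 at +0.26 (SE 0.07) and the small heat shock protein gene Hspb6 at +0.18 (SE 0.06). Of its members 1 passed adjusted over the list alone (Ppp1r14a, p 0.016); over all genes 0 did in limma, where these 3 had adjusted p-values of 0.095, 0.135 and 0.159, and 8 members had an unadjusted p under 0.05. The list passed camera (adjusted p 0.024) but had an adjusted p = 0.660 with an estimated correlation and 0.297 in fry. The call was lost without wild type replicate 3 (median 0.034, adjusted p 0.268), knockout replicate 1 (0.069, adjusted p 0.082) or knockout replicate 4 (0.092, adjusted p 0.077). It was also lost with the adipocyte markers as a covariate (0.024, adjusted p 0.306) and without the 2 arrays with most neuronal transcripts (0.025, adjusted p 0.463).

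Of the 33 lists, 16 passed camera, 15 of them toward lower values in the knockout, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. In fry, which asks whether a list's genes move on balance one way, 1 passed and 5 had an unadjusted p under 0.05. 0 members of any list passed over all genes in limma. At an unadjusted p under 0.05 there were 134, where 719 genes of the lists and sample checks together were tested. That is no larger a share than the 2847 of all 14321 tested genes. Counts of list members at that p, above and below, are to be read against this share.

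Heat shock genes lay lower in the knockout aortas in 17 of 17 tested members, with a median of −0.35. Hspb1, a small heat shock protein, stood at −0.54 (SE 0.09), the co-chaperone gene Dnaja1 at −0.37 (SE 0.07) and Hspa1a, the inducible HSP70, at −1.02 (SE 0.24), all with adjusted p-values over all genes of 0.083 to 0.118 (limma). The mean of the list was 11.83 to 12.12 on the 4 wild type arrays and 11.55 to 11.68 on the 5 knockout arrays. 13 members passed adjusted over the list alone, all lower, and 13 had an unadjusted p under 0.05. The list passed camera (adjusted p 4.2e-12) and fry (adjusted p 0.019), with an adjusted p = 0.427 with an estimated correlation.

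Glucocorticoid targets were lower in 16 of 16 members, with a median of −0.36. Fkbp5, a chaperone of the glucocorticoid receptor, stood at −1.44 (SE 0.28), Tsc22d3, the glucocorticoid-induced leucine zipper, at −0.74 (SE 0.20) and Pdk4, a pyruvate dehydrogenase kinase, at −0.19 (SE 0.05). 5 targets passed adjusted over the list alone, all lower, against 6 at an unadjusted p under 0.05. Camera gave an adjusted p of 3.8e-07 and an adjusted p = 0.555 with an estimated correlation. The mean of the list on knockout replicate 4, 11.33, lay within the wild type range of 11.21 to 11.47, and the other knockout arrays lay between 10.70 and 10.95.

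Immediate early genes were lower in 25 of 30 members, with a median of −0.15 and a mean of −0.34. Arc, induced by neuronal activity and serum, stood at −1.57 (SE 0.34), the cytokine signalling inhibitor Socs3 at −0.80 (SE 0.23) and Ier5 at −0.83 (SE 0.24). Arc alone passed adjusted over the list alone, 1 of 30, and 6 had an unadjusted p under 0.05. Camera gave an adjusted p of 8.9e-05 and an adjusted p = 0.594 with an estimated correlation. Wild type replicate 1 lay at 9.61, below every knockout array (9.66 to 10.26) and the other wild type arrays (10.49 to 10.68). The median was −0.43 without it, −0.09 without wild type replicate 5 or knockout replicate 1, −0.25 without knockout replicate 5, and −0.036 without the 2 arrays with most neuronal transcripts, where the call was lost (adjusted p 0.101).

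Genes of the unfolded protein response were lower in 16 of 20 members (median −0.11). Asns, asparagine synthetase, stood at −0.51 (SE 0.12), Chac1, which degrades glutathione, at −0.96 (SE 0.23) and the co-chaperone gene Dnajb9 at −0.24 (SE 0.07). 5 members passed adjusted over the list alone, all lower, among 6 with an unadjusted p under 0.05. Camera gave an adjusted p of 0.00030 and an adjusted p = 0.532 with an estimated correlation.

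Lists of energy and lipid metabolism also lay lower. Fatty acid oxidation genes were lower in 22 of 23 members (median −0.24): Angptl4, a lipase inhibitor and PPAR target, stood at −0.76 (SE 0.16) and Ehhadh, a peroxisomal enzyme of β-oxidation, at −0.83 (SE 0.21). Camera gave this list an adjusted p of 2.2e-07 and an adjusted p = 0.594 with an estimated correlation. Oxidative phosphorylation genes were lower in 39 of 42 members (median −0.12), among them Uqcrc1 of complex III at −0.46 (SE 0.16), Ndufa10 of complex I at −0.32 (SE 0.12) and Sdha of complex II at −0.12 (SE 0.05); camera gave an adjusted p of 1.3e-06 and an adjusted p = 0.594 with an estimated correlation. Cholesterol synthesis genes were lower in 15 of 18 members (median −0.20), among them Pmvk at −0.96 (SE 0.22), Fdft1 at −0.44 (SE 0.12) and Cyp51 at −0.43 (SE 0.13), with an adjusted p of 0.00028 in camera and an adjusted p = 0.594 with an estimated correlation. Genes of hypoxia and glycolysis were lower in 18 of 22 members (median −0.15), among them Bnip3, which acts in mitophagy, at −0.28 (SE 0.07), the collagen prolyl hydroxylase gene P4ha2 at −0.35 (SE 0.12) and Higd1a at −0.13 (SE 0.05), with an adjusted p of 0.00025 in camera and an adjusted p = 0.532 with an estimated correlation. Adjusted over the list alone, 3 fatty acid oxidation genes passed (Angptl4, Ehhadh and Pdk4), with 0 in oxidative phosphorylation, 2 in cholesterol synthesis (Pmvk and Fdft1) and 1 in hypoxia and glycolysis (Bnip3); at an unadjusted p under 0.05 there were 10, 3, 7 and 5. Without wild type replicate 3 the median was −0.14 for fatty acid oxidation, −0.053 for oxidative phosphorylation and −0.098 for cholesterol synthesis. The cholesterol median was −0.11 without wild type replicate 1 and −0.30 without wild type replicate 5, and the oxidative phosphorylation median −0.077 without knockout replicate 5.

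Adipocyte markers lay lower beside these metabolic genes. General adipocyte markers were lower in 20 of 23 members (median −0.16), among them Lpin1, a phosphatidate phosphatase, at −0.49 (SE 0.11), the triglyceride lipase gene Pnpla2 at −0.46 (SE 0.14) and Pparg at −0.38 (SE 0.14). Brown adipocyte markers were lower in 15 of 17 members (median −0.27), among them Plin5 at −0.39 (SE 0.10), Slc27a2 at −0.63 (SE 0.21) and Fabp3 at −0.70 (SE 0.26). Camera gave adjusted p-values of 0.00030 and 0.00033, and both had an adjusted p = 0.594 with an estimated correlation. 1 general marker (Lpin1) and 0 brown markers passed in limma adjusted over the list alone, against 4 and 6 with an unadjusted p under 0.05. The mean of the general markers was 11.42 ± 0.31 (SD, n = 5) in the knockout and 11.61 ± 0.06 (SD, n = 4) in wild type, with the lowest values on knockout replicates 5 (10.93) and 1 (11.30); the exact permutation p was 0.325. The general median was −0.069 without knockout replicate 5 and −0.094 without wild type replicate 5. With the adipocyte markers as a covariate, 5 lists passed: heat shock (median −0.27), immediate early genes (−0.27), glucocorticoid targets (−0.25), endothelial markers (−0.25) and fatty acid oxidation (−0.081). The other 11 no longer did: oxidative phosphorylation then stood at 0.0066 (adjusted p 0.990), hypoxia and glycolysis at −0.032 (0.176), cholesterol synthesis at −0.071 (0.060), the unfolded protein response at −0.064 (0.060), contractile genes at 0.024 (0.306) and interferon genes at −0.066 (0.338). Inflammation genes stood at −0.12 (adjusted p 0.230), macrophage markers at −0.20 (0.096), neuron markers at −0.82 (0.176), and the adipocyte lists, which make up the covariate, at −0.026 (brown, 0.483) and 0.037 (general, 0.899).

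**Figure D2:**
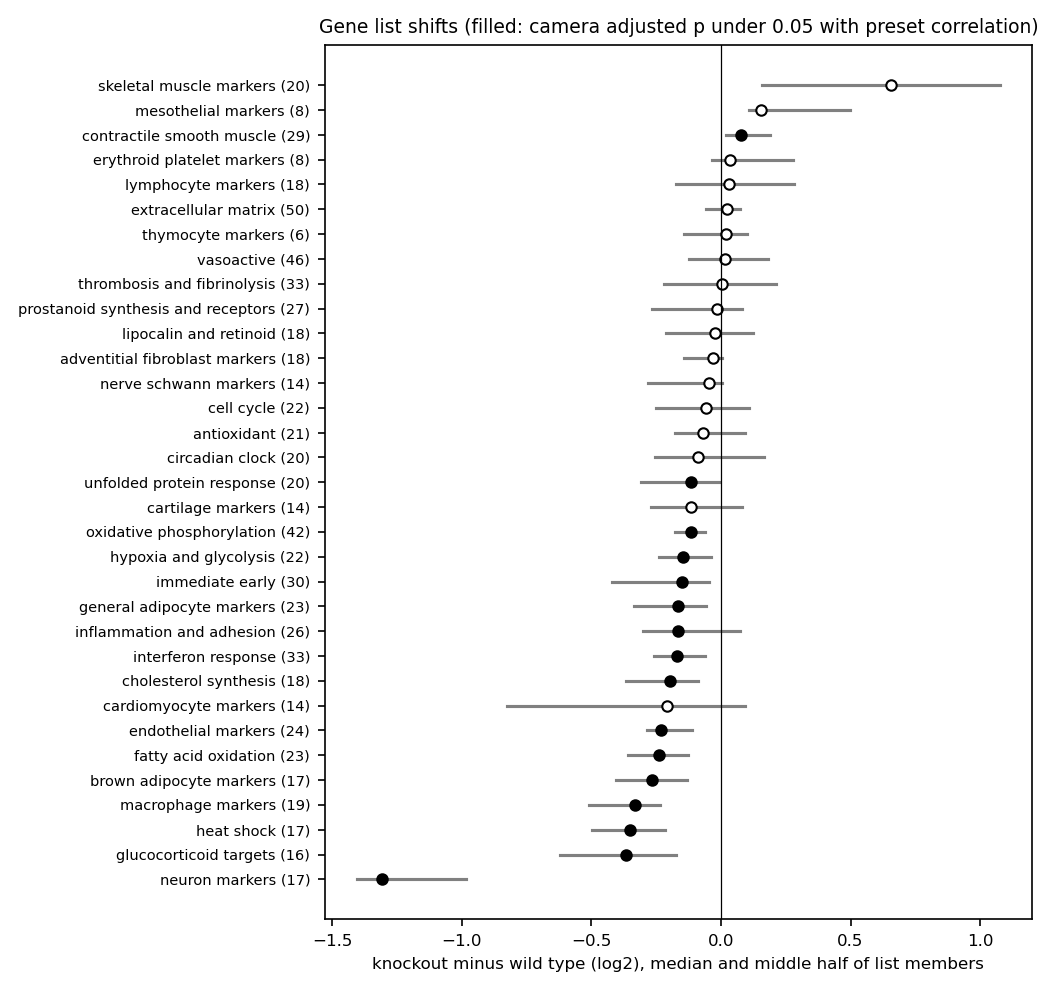
Median change, knockout minus wild type (log2), of each of the 33 gene lists, with the middle 50% of its tested members as a line and their number in brackets; filled points passed camera with the preset correlation. Of the 16 filled points 15 lie below 0, and contractile smooth muscle lies above it at 0.077.

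Endothelial and macrophage markers lay lower as well. Those of endothelium were lower in 20 of 24 members (median −0.23), among them Cdh5, the endothelial cadherin, at −0.34 (SE 0.09), the adhesion molecule gene Esam at −0.24 (SE 0.08) and endomucin Emcn at −0.50 (SE 0.17). Macrophage markers were lower in 18 of 19 members (median −0.33), among them Lyve1 at −0.56 (SE 0.23) and Cd14 at −0.49 (SE 0.20), while Cbr2, a carbonyl reductase, stood at +0.27 (SE 0.08). Camera gave adjusted p-values of 5.2e-05 and 0.00051, and both had an adjusted p = 0.594 with an estimated correlation. Adjusted over the list alone 0 members of either passed in limma, and unadjusted p-values under 0.05 numbered 8 and 5. The macrophage median was −0.56 without wild type replicate 4 and −0.20 without wild type replicate 5.

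Interferon response genes and genes of inflammation and adhesion passed camera toward lower values, and both calls were lost under several settings. Interferon genes were lower in 28 of 33 members (median −0.17): the class I histocompatibility genes H2-K1 and H2-D1 stood at −0.29 (SE 0.09) and −0.22 (SE 0.09), and Ddx58, the RNA sensor RIG-I, at +0.32 (SE 0.15). Camera gave an adjusted p of 0.0022 and an adjusted p = 0.660 with an estimated correlation. The list's mean was 9.29 on wild type replicate 3 and 8.33 to 8.53 on the other 8 arrays, and without that array the median turned to +0.048 (adjusted p 0.938); it was −0.25 without wild type replicate 4 and −0.26 without wild type replicate 5. Genes of inflammation and adhesion were lower in 18 of 26 members (median −0.16), among them the chemokine gene Ccl9 at −0.76 (SE 0.22) and Il1rn, the interleukin 1 receptor antagonist, at −1.20 (SE 0.39), with pentraxin Ptx3 at +0.40 (SE 0.15). Camera gave an adjusted p of 0.030 and an adjusted p = 0.594 with an estimated correlation. That call was lost without wild type replicate 3 (−0.081, adjusted p 0.072), wild type replicate 5 (−0.051, adjusted p 0.298), knockout replicate 1 (−0.16, adjusted p 0.060) or knockout replicate 2 (−0.15, adjusted p 0.104). With all arrays kept it was lost with array medians set to 0 (−0.19, adjusted p 0.056) and with the Gapdh 3' minus 5' difference as a covariate (−0.13, adjusted p 0.068). Adjusted over the list alone 0 members of either passed in limma, and unadjusted p-values under 0.05 numbered 2 and 3.

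Neuron markers were present on some arrays of both groups. Their mean was 10.86 on wild type replicate 3, 9.25 on knockout replicate 1 and 7.69 on wild type replicate 4, and 4.86 to 5.98 on the other 6 arrays. All 17 members were lower in the knockout on average (median −1.31), among them Uchl1 at −0.53 (SE 0.39), Stmn2 at −0.98 (SE 0.80) and Stmn3 at −1.79 (SE 1.57), and 0 passed in limma adjusted over the list alone or had an unadjusted p under 0.05. Camera gave an adjusted p of 0.0063 and an adjusted p = 0.660 with an estimated correlation, and the exact permutation p of the group difference was 0.413. The median was −0.00085 without wild type replicate 3, where the call was lost (adjusted p 0.612), −2.12 without wild type replicate 5 and −2.20 without knockout replicate 1. Without both wild type replicate 3 and knockout replicate 1 it was −0.81 and the list still passed (adjusted p 0.00058 in camera). That remainder rests mainly on wild type replicate 4, since wild type replicates 1 (5.98) and 5 (4.89) lay near or within the range of knockout replicates 2 to 5 (4.86 to 5.94).

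**Figure D3:**
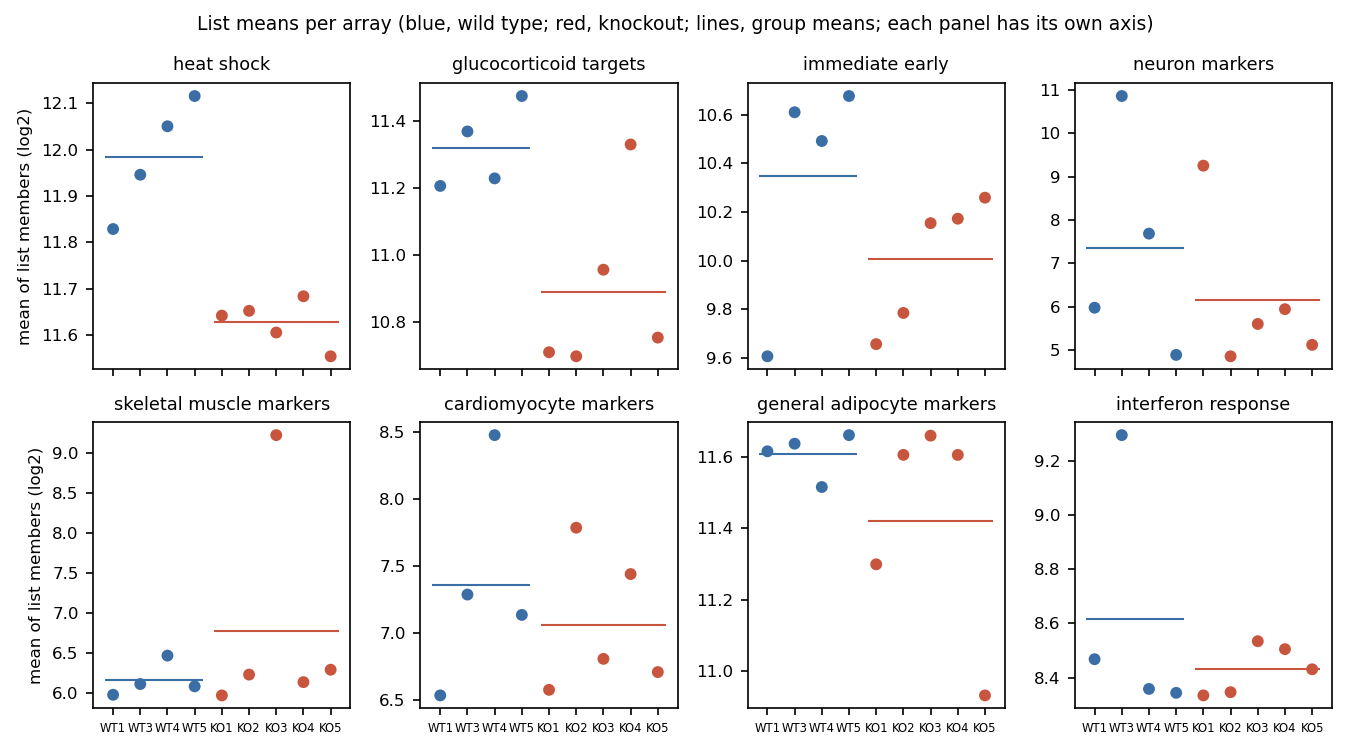
Mean log2 value of the members of 8 gene lists on each array, with wild type (WT) in blue, knockout (KO) in red, the group means as lines and an axis for each panel. Heat shock genes lie at 11.83 to 12.12 on wild type and 11.55 to 11.68 on knockout arrays, while neuron markers are highest on wild type replicate 3 (10.86) and knockout replicate 1 (9.25).

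The other lists did not pass camera. Skeletal muscle markers had a median of +0.66 (adjusted p 0.226), with a mean of 9.22 on knockout replicate 3 and 5.97 to 6.47 on the other arrays, and cardiomyocyte markers a median of −0.21 (adjusted p 0.326), with their highest means on wild type replicate 4 (8.48) and knockout replicate 2 (7.79). Without any 1 array these medians ran from 0.036 to 0.85 and from −0.42 to 0.063. The adjusted p was 0.159 for cell cycle genes (median −0.056), 0.166 for cartilage markers (−0.11), 0.204 for circadian clock genes (−0.089) and for antioxidant genes (−0.071), 0.272 for adventitial fibroblast markers (−0.032), 0.278 for Schwann cell markers (−0.046), 0.405 for lipocalin and retinoid genes (−0.024) and 0.538 for mesothelial markers (+0.15). It was 0.331 for thymocyte markers (median 0.018, mean −0.023). For erythroid and platelet markers (0.034), lymphocyte markers (0.029) and extracellular matrix genes (0.024) it was 0.753. Camera placed the thymocyte, lymphocyte and matrix lists lower although their medians were above 0. It compares a list with the other genes, and the median change over all tested genes was 0.027. Leaving out 1 array also turned the sign of the median for cell cycle, matrix, lipocalin and retinoid, fibroblast, Schwann cell, lymphocyte and thymocyte lists. Cell cycle genes passed without knockout replicate 5 (−0.092, adjusted p 0.047), adventitial fibroblast markers without wild type replicate 4 (−0.19, adjusted p 0.0016) and Schwann cell markers without wild type replicate 5 (−0.31, adjusted p 0.025). When adjusted over the list alone, 7 of 20 clock genes and 4 of 21 antioxidant genes passed, and 0 in the other lists of this paragraph (limma), where 0 to 5 members each had an unadjusted p under 0.05.

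0 of 16 measures of tissue makeup and RNA quality per array differed between the groups at an unadjusted p under 0.05. Endothelial markers differed by −0.19 (exact permutation p 0.087), brown adipocyte markers by −0.35 (exact permutation p 0.071) and macrophage markers by −0.33 (exact permutation p 0.135). The 3' minus 5' difference of the Gapdh controls was 2.80 ± 0.38 (SD, n = 4) in wild type and 2.86 ± 0.26 (SD, n = 5) in the knockout (exact permutation p 0.762), and that of the Actb controls 2.47 ± 0.16 and 2.61 ± 0.13 (exact permutation p 0.198). The smallest adjusted p was 0.529, but with 16 measures and 126 splits 1 measure alone could not reach an adjusted p under 0.127, so a difference in a single measure stays open.

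A targeted allele can carry neighbouring DNA of the strain it was made in, so genes near Ptgds were examined. Of the 200 tested genes nearest to Ptgds in gene order 0 were called, against 7 of 14120 others (Fisher's exact test, two-sided, p 1); the others include 34 genes without a known position, Pisd-ps3 among them. At an unadjusted p under 0.05 there were 44 of the 200 (22%) and 19.8% of the others, an odds ratio of 1.14 (Fisher's exact test, two-sided, p 0.475). Without wild type replicate 1 the count of called neighbours was 18 (p 0.339 in the same test).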

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

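The tests of DNA kept around Ptgds, of blocks of neighbouring genes, of the label of wild type replicate 1 and of genotype for the neuron markers were chosen only after the result was seen, as were the clock genes Nr1d1, Wee1, Usp2 and Npas2.

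Of 240 groups of arrays examined, 20 held 1 array whose gap to its nearest neighbour was large for the group's range, where chance gives about 12, or 1 in 20. Among neuron markers these were the list's mean on knockout replicate 1 (9.25, others 4.86 to 5.94), Stmn2 on that array (8.44) and Uchl1 on wild type replicate 3 (11.59). On knockout replicate 3 skeletal muscle markers averaged 9.22 (others 5.97 to 6.29) and Socs3 stood at 7.01. On wild type replicate 3 interferon response genes averaged 9.29 (others 8.34 to 8.47), fatty acid oxidation genes 11.68, and Cndp2 stood at 12.00. On knockout replicate 4 the clock genes Nr1d1 (9.61), Wee1 (10.32), Usp2 (12.07) and Npas2 (6.93) stood apart from the other knockout arrays, as did Akap5 (6.09) and Chac1 (7.23). The others were Bnip3 (12.82) and Pmvk (10.66) on wild type replicate 1, Anxa2 (11.74) on wild type replicate 4, Esam (8.12) on knockout replicate 1, and Asns (10.96) and Pparg (10.75) on knockout replicate 5.

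The first pattern is the set of 7 genes called beside Ptgds. Of 100 splits of the arrays into 4 and 5, 2 gave at least the real 8 calls, a share under 0.05. The real split is 1 of these 2. The other, with wild type replicates 3, 4 and 5 beside knockout replicate 4, gave 23. Since a mixed grouping called more genes than the genotypes did, the count cannot tell genotype from a structure of the samples. DNA of another strain kept around the targeted gene is argued against, since 0 of the 6 with a known position lie within 250 tested genes of Ptgds (Pisd-ps3 has none). Strain differences elsewhere may be involved, as Nnt is known to carry a deletion in the C57BL/6J substrain and Mid1 and G530011O06Rik are neighbours, but the 4 pairs of neighbours among genes at an adjusted p under 0.10, against a median of 2 and a share of 0.199 of 10000 random draws with as many, leave this open. Sequence differences under single probe sets stay open too, since a share of 0.538 of 52 other probe sets of those genes moved the same way at an unadjusted p under 0.05. The labels give no substrain for either group, so an effect of losing Ptgds and a difference in background cannot be told apart for these genes.

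The second pattern is the lower stress and metabolic lists together with wild type replicate 1: as many lists as the real 16 passed in 30 of 100 splits, with up to 21 in another, so chance cannot be excluded for the number of lists. Less fat on the knockout aortas is argued against as the whole cause for the 3 stress lists, whose mean change kept 92.0% of its size (−0.29 to −0.27) with the fat markers as a covariate, although heat shock went from −0.35 to −0.27, glucocorticoid targets from −0.36 to −0.25 and immediate early genes from −0.15 to −0.27. For fatty acid oxidation and oxidative phosphorylation only 20.9% was kept (−0.18 to −0.04), as less fat would give. This cannot decide for less fat, since the fat markers themselves include metabolic genes such as Ppargc1a and Fabp3. The covariate could take up a fall in these lists with or without less fat. With the Gapdh control difference as a covariate, 95.4% of the change in the 5 lists was kept. That difference was nearly equal in wild type (2.80) and knockout (2.86), so this covariate could hardly move the change. The Actb control difference (2.47 and 2.61) was not used as a covariate, so RNA degradation is not excluded. A wrong label of wild type replicate 1 is argued against, since Ptgds there lay 4.71 above the highest knockout array. An effect of genotype on the stress lists and a difference in handling, of which the labels give no record, stay open and untested.

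The third pattern is neuronal transcripts, which were highest on wild type replicate 3 and knockout replicate 1. A candidate source is sympathetic ganglion tissue carried over at dissection. There, 12 tested genes of a second list of 17 neuronal genes lay at a median of 2.45 and 1.27 above the other arrays. Th, Dbh, Npy and Snap25 stood at 11.28, 11.57, 12.30 and 12.59 on wild type replicate 3. On knockout replicate 1 they stood at 9.18, 9.31, 11.33 and 11.39. They are not among the 12, and the arrays were picked for neuronal transcripts, so these levels add no support of their own. The aorta itself had high levels of some genes of the second list, such as Dpysl3 at 12.40 and Map1b at 10.70 on the other arrays. Adrenaline-making cells of the adrenal medulla are argued against, since Pnmt lay at −0.87 and −0.15 against the other arrays. But Slc18a1, a vesicle transporter of chromaffin cells and 1 of the 12 genes, lay at 4.07 and 1.40 there. Chromaffin cells without Pnmt therefore stay open, and the second list does not separate them fully from ganglion tissue. Genotype is argued against as the sole cause, since each group holds arrays with and without these transcripts (exact permutation p 0.413). Without both arrays the neuron list stayed lower in the knockout (median −0.81, adjusted p 0.00058 in camera). That remainder rests mainly on wild type replicate 4, which held these transcripts at lower levels (Th 7.17, Dbh 7.86, Npy 9.89 and Snap25 9.96). Resting on 1 array, it cannot speak for an effect of genotype.

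Near Ptgds, 44 genes had an unadjusted p under 0.05, a count that 1 of 100 splits reached (the real one, highest other 36). Genes elsewhere showed a like excess, 19.8% against 22% (Fisher's exact test, two-sided, p 0.475), so the count says nothing about the region itself.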

How the results depend on the processing

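The settings on neuronal transcripts and on the Gapdh controls were chosen after seeing the data. Wild type replicate 2 could not be added, since its column holds no values. The 8 called genes became 19 with a floor of 6, 16 with every probe set tested, 33 with trend and robust options and 73 with array weights (all 8 shared in each), 86 at an adjusted p under 0.10, 3 without the 2 arrays with most neuronal transcripts and 2 to 1051 without any 1 array; fewer arrays and the looser threshold account for part of this, and the cause was otherwise not tested. The replicate number as a block gave 0, and the other settings gave 6 to 10. Lists past the threshold numbered 16, and 5 with the adipocyte covariate, 0 with an estimated correlation, 1 in fry and 12 to 18 elsewhere. The prostanoid median ranged from −0.11 to 0.013 without any 1 array. Over all tested genes the median change was 0.027 as deposited and 0.0040 with array medians set to 0. The contractile median was 0.053 with array medians set to 0, 0.044 with array weights, 0.024 with the adipocyte covariate, 0.025 without the neuronal arrays and 0.069 with the neuron covariate, each no longer past (adjusted p 0.054 to 0.463), stayed at 0.077 with an estimated correlation and in fry (adjusted p 0.660 and 0.297), and was 0.034 to 0.11 without any 1 array; with the mean of a gene's probe sets it rose to 0.12 (adjusted p 0.0033), and the cause was not tested. Array weights also ended the calls of interferon genes (−0.070, adjusted p 0.127) and neuron markers (−0.43, adjusted p 0.206), and moved the medians of cholesterol synthesis (−0.20 to −0.033), oxidative phosphorylation (−0.12 to −0.054), fatty acid oxidation (−0.24 to −0.13), hypoxia and glycolysis (−0.15 to −0.094), general adipocyte markers (−0.16 to −0.089) and immediate early genes (−0.15 to −0.33), all still past. The interferon median turned to 0.048 without the neuronal arrays and ran from −0.26 to 0.048 without any 1 array. Without the neuronal arrays inflammation genes no longer passed (−0.069, adjusted p 0.131), and oxidative phosphorylation stood at −0.057, fatty acid oxidation at −0.14 and brown adipocyte markers at −0.17, all still past. With the neuron covariate interferon genes no longer passed (−0.054, adjusted p 0.066) and cholesterol synthesis stood at −0.12, still past. The general adipocyte list turned to 0.037 with the mean of both adipocyte lists as a covariate, by construction. Eif2s3y, unchanged in the test, turned to −0.098 with the mean of its probe sets and ran from −0.00062 to 0.070 without any 1 array. Called genes near Ptgds numbered 0 to 18 without any 1 array, and 44 at an unadjusted p under 0.05. Without a filter the inflammation median was −0.10, still past (adjusted p 0.013). Cartilage markers passed without a filter (−0.13) and with the neuron covariate (−0.17), and antioxidant genes with every probe set tested (−0.12). With the replicate number as a block 0 genes passed in limma (1963 at an unadjusted p under 0.05) and Ptgds stood at −5.30 (adjusted p 0.126); the block also put the prostanoid list past the threshold (−0.056, adjusted p 0.036), put cardiomyocyte markers past it (−0.32, adjusted p 0.019) and took inflammation genes out (−0.15, adjusted p 0.093), for 17 lists in all. To check for pairing, each gene's group mean was subtracted before arrays were correlated. Same-numbered arrays then correlated at −0.36 to 0.21, and 2 of 8 arrays correlated best with their own number. That is no sign that the numbers pair the samples. The highest of these correlations, 0.67, was between wild type replicate 3 and knockout replicate 1, the arrays with most neuronal transcripts. Such differences in tissue can hide a pairing, so the check cannot exclude it. Dim probe sets limit what can be seen: about 70.1% to 71.4% lay over a log2 value of 4.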

Other observations

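The clock and antioxidant genes, and the genes listed for the fit without wild type replicate 1, were chosen only after their values were seen; leaving out each array was planned.

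Genes of the circadian clock went both ways, and 7 of 20 passed when adjusted over the list alone, with 0 over all genes in limma. Higher in the knockout were Nr1d1, which encodes the repressor REV-ERBα, at +0.67 (SE 0.16), its target Npas2 at +0.56 (SE 0.18) and the output gene Dbp at +0.29 (SE 0.09). Lower were Nfil3 at −0.91 (SE 0.30), which acts against Dbp on shared DNA sites, the deubiquitinase gene Usp2 at −0.76 (SE 0.21), the repressor gene Cry1 at −0.62 (SE 0.17) and the cell cycle kinase gene Wee1 at −0.51 (SE 0.13). The list as a whole had a median of −0.089 and did not pass camera (adjusted p 0.204). Knockout replicate 4 had Nr1d1 at 9.61, Wee1 at 10.32, Usp2 at 12.07 and Npas2 at 6.93, where the wild type means were 9.44, 10.42, 12.14 and 6.92; the labels give the light schedule but no hour of dissection. Among antioxidant genes, adjusted over the list alone, the glutathione transferase genes Gstm2 (+0.30, SE 0.08) and Gstm1 (+0.23, SE 0.07) were higher and Hmox1 (−0.43, SE 0.12) and sulfiredoxin Srxn1 (−0.37, SE 0.10) lower.

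Without wild type replicate 1, 1051 genes passed in limma, 750 higher and 301 lower in the knockout, among them all 8 called on 9 arrays. Of 30 immediate early genes 9 were lower, among them Arc (−1.94, SE 0.22) and Ier5 (−1.12, SE 0.09), and of 17 heat shock genes 7 were lower, among them Hspa1a (−1.29, SE 0.13) and Bag3 (−0.76, SE 0.08). Rcan1, an inhibitor of calcineurin, stood at −1.23 (SE 0.08) and the hyaluronan-binding protein gene Tnfaip6 at −1.79 (SE 0.17). Ptgs2, the inducible cyclooxygenase, was lower, 1 of 27 prostanoid genes. Higher were Gucy1a1 and Ramp1, 2 of 46 vasoactive genes, and Itgb3, 1 of 33 genes of thrombosis and fibrinolysis. So were Myl9, Lmod1 and Ppp1r14a, 3 of 29 contractile genes. Such counts are to be read against 1051 of 14321 tested genes, and only the contractile share lies above that. Wild type replicate 1 lay nearer to the knockout mean for 82.7% of the 1051 genes, at a median position of 0.19 between the knockout mean (0) and the mean of the other wild type arrays (1). Leaving out the array that lies nearest to the other group widens the difference by construction, so this count is no independent evidence. Over genes with an unadjusted p under 0.05 in the fit of all 9 arrays, the median position was 0.22 for wild type replicate 1, 1.07 for replicate 3, 0.61 for replicate 4 and 1.16 for replicate 5.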
